A study of Homo sapiens with 32 samples.

How the data were processed

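The series measured polyadenylated RNA in 2 human germ cell cancer cell lines, NTera2 (embryonal carcinoma-derived) and TCam-2 (seminoma-derived). Per the labels, the cells were given vehicle (D-PBS), RANKL, OPG or denosumab for 48 h in culture medium with serum. Denosumab stands in the titles and treatment labels of its libraries, but the protocol does not name it and lists RANKL again in its place, so what these libraries received rests on their labels alone. RANKL is the ligand of the receptor RANK, and OPG and the antibody denosumab both bind RANKL and keep it from the receptor. The protocol gave 1 µg/ml for RANKL and OPG, and no dose under the name of denosumab. Each of the 8 groups held 4 libraries, which came from 4 independent experiments per the labels, so n is 4 throughout unless another number is given.

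Per the labels' protocols, stranded libraries were sequenced as paired 52-bp reads. Per the submitters' processing notes, the authors demultiplexed with bcl2fastq 2.20.0, aligned to GRCh38/hg38 with STAR 2.7.9a and counted reads per gene with featureCounts 1.6.2. The deposited values were therefore raw read counts per gene, and their whole-number form was checked. The deposited table also gave a gene length, chromosome, start and end for each gene in a form other than a count. The lengths were not used here. The annotation release and the strand setting of the counting were not given in the sources used here. Antisense and overlapping genes are therefore uncertain, among them MT-ATP8 with MT-ATP6 and MT-ND4L with MT-ND4, which overlap on one strand. Genes with near-identical copies are uncertain too, such as HLA, histone, ribosomal protein, XAGE, KRT8, KRT18, HSPA1A and POU5F1 with its pseudogenes, and mitochondrial genes with nuclear copies.

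All 32 libraries were matched to a sample, and 0 columns were left over. The table held 61541 genes, of which 35258 carried a symbol and 61369 matched the gene name table by identifier. Total counts per library ranged from 11385500 to 30499538 in NTera2 and from 10585247 to 20257935 in TCam-2. The RNA integrity number (RIN) given by the labels was 8.3 or higher except in TCam-2 RANKL replicate 2 (6.1) and replicate 4 (3.7), and NTera2 vehicle replicate 1 had none. Any 2 libraries of a group differed by more than counting noise, with a chi-square per degree of freedom between 2.57 and 17.55.

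Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM normalization, robust quasi-likelihood F test) and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called a change. The standard error (SE) of a log2 fold change was its size divided by the square root of F. With no effect, a share of about 0.05 of the genes tested is expected at an unadjusted p under 0.05. The tests, samples, gene lists and naming rule were fixed before the data were examined. The 16 libraries of a line were fitted together for the comparisons of each treatment with vehicle and of each inhibitor with RANKL. All 32 libraries were fitted for the interactions of line and treatment, and the 8 vehicle libraries for TCam-2 against NTera2, which made 14 comparisons. Counts-per-million values (CPM) used TMM factors over all 32 libraries and are given as mean ± SD of 4 libraries. A group without counts was given a floor of 3 counts over the group. Folds against such a group are bounds against that floor, and a ratio to a group with 1 to 3 counts carries an exact 95% counting interval. Intervals and floors cover counting error only.

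There were 24 gene lists: RANKL axis and RANK signalling, NF-kB targets, osteoclast genes downstream of RANK, cell cycle and proliferation, p53 targets and apoptosis, pluripotency, embryonal carcinoma markers, seminoma and primordial germ cell markers, somatic and extraembryonic differentiation, cancer-testis genes, interferon response, integrated stress and unfolded protein response, heat shock and proteotoxic stress, hypoxia and glycolysis, cholesterol synthesis, immediate early genes, WNT and TGF-beta family targets, epithelial, mesenchymal and invasion genes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, and markers of fibroblasts, of immune cells and of Sertoli, Leydig and endothelial cells. Lists with at least 5 tested members (22 of 24) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for the 6 treatment comparisons and the line comparison. Camera compares the members of a list with all other genes, so a list said below to rise or fall did so relative to them. Fry tests whether the members move on balance one way, and its mixed form whether they change in either direction, and neither compares a list with other genes. Counts of members adjusted over the list alone are given beside list results.

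Genes were named by a fixed rule. TNFSF11, TNFRSF11A and TNFRSF11B were named everywhere. In a treatment, inhibitor or interaction comparison the rule named the 10 largest called changes in each direction (mean CPM of at least 1, same sign in all 4 pairs), or, with fewer than 10 calls, the 10 genes with the smallest p. In the line comparison it named the 10 largest changes in each direction (mean CPM of at least 10 in the higher line, no overlap of libraries). From each list past its test up to 4 members were named, and from other lists up to 2, by smallest p, and a part of these is printed here. Features without an approved gene symbol and genes of the Y chromosome and XIST were left out, and some further genes that the rule named are not reported here.

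Libraries of a line with the same replicate number carried the same passage number per the labels (27, 29, 30 and 31 in NTera2, 118, 120, 121 and 122 in TCam-2), and this shared passage was taken as pairing. In the check of the pairing, deviations from group means of same-numbered libraries had a mean correlation across genes of 0.244 in NTera2 (range -0.177 to 0.652, 10512 genes) against -0.0815 for different numbers. In TCam-2 the values were 0.181 (range -0.32 to 0.512, 9817 genes) against -0.0586. Genes are not independent replicates. Deviations within a group cancel out, so the values for different numbers follow from those for the same numbers and are no second measure. Of the 16 libraries of a line, 11 in NTera2 and 12 in TCam-2 lay closest to a library of their own number. These values were not tested against chance.

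Each comparison was repeated with other settings. Chosen beforehand were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, each library left out in turn, only the 8 libraries compared, fits without or adjusted for the libraries with a RIN under 7, all 32 libraries for the line comparison, and camera with an estimated correlation or fry in place of the preset correlation. Chosen after seeing the data were a spline correction for GC content and transcript length from GENCODE 29 (98.1% of genes had values), the same with the block, fits without the 2 libraries per line farthest from their groups, camera with the block and an estimated correlation, camera with each library left out, and list tests of the interactions and of the inhibitors against RANKL.

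The test was tested on simulated data with 50 changed genes per fold size among 16244 to 18900 genes per comparison. The changed genes had a mean CPM of at least 1, and all fold sizes were changed in the same simulated libraries. Against vehicle, a 2-fold change was recovered for 76% of genes for RANKL, 76% for OPG and 86% for denosumab in NTera2, and for 78%, 80% and 88% in TCam-2. For a 1.5-fold change the shares in that order were 68%, 64%, 66%, 66%, 62% and 52%, for a 1.25-fold change 30%, 34%, 14%, 24%, 14% and 30%, and for a 4-fold change 98%, 94%, 92%, 100%, 96% and 98%. Against RANKL, a 2-fold change was recovered for 84% (OPG) and 78% (denosumab) in NTera2 and 78% and 88% in TCam-2. For the interactions with RANKL, OPG and denosumab it was 66%, 52% and 66%, and for the line comparison 84%. The share of false calls lay between 0.741% and 7.69%. Camera called a simulated shift of 0.25 in log2 of the cell cycle list in all 7 comparisons and no other list. The simulated genes varied independently and without pairing, so this does not test the preset correlation or false calls among correlated genes. Recovery was not simulated for genes of lower CPM or with fewer changed genes, so the shares do not cover these cases. For the line comparison the unchanged genes had the same mean in both lines, unlike the real libraries.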

Results

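RNA was sequenced from NTera2 cells, a line derived from embryonal carcinoma, and TCam-2 cells, a line derived from seminoma. Both lines were grown for 48 h with vehicle, with RANKL, or with OPG or denosumab, which both block RANKL. Each of the 8 groups held 4 libraries from independent experiments, 32 in all. Total counts per library lay between 11385500 and 30499538 in NTera2 and between 10585247 and 20257935 in TCam-2. The number of genes with counts lay between 21729 and 26730 in NTera2 and between 21296 and 26017 in TCam-2.

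The first question was whether either line expressed the genes of the RANKL axis. TNFRSF11A (ENSG00000141655, RANK, the receptor; hg38 chromosome 18, 62325287 to 62387659) was present in both lines, at 7.32 ± 0.807 CPM in NTera2 vehicle libraries and 2.18 ± 1.04 CPM in TCam-2 vehicle libraries. TNFSF11 (ENSG00000120659, RANKL; chromosome 13, 42562736 to 42607174) was at 1.71 ± 0.438 CPM in NTera2, whereas the TCam-2 vehicle libraries held 6 counts in all and 3 of the 4 had none. TNFRSF11B (ENSG00000164761, OPG; chromosome 8, 118923557 to 118951885) was at 1.67 ± 0.132 CPM in NTera2 and had no counts in TCam-2 vehicle, where the floor of 3 counts over the group corresponded to 0.06 CPM. All 3 genes were lower in TCam-2 than in NTera2 in edgeR's test. The log2 fold change was -3.75 (SE 0.686, adjusted p = 0.000105) for TNFSF11 and -1.72 (SE 0.276, adjusted p = 2.69e-05) for TNFRSF11A, and TNFRSF11B was at least 27.9-fold lower (adjusted p = 1.09e-06).

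None of the 3 genes passed edgeR's threshold in a treatment comparison. In NTera2 with RANKL, TNFSF11 was at 2.25 ± 0.403 CPM (log2 fold change 0.39, SE 0.276, adjusted p = 0.614), TNFRSF11B at 2.27 ± 0.289 CPM (0.46, SE 0.28, adjusted p = 0.557, higher in 4 of 4 pairs) and TNFRSF11A at 7.05 ± 0.546 CPM (-0.03, SE 0.146, adjusted p = 0.949). With OPG the log2 fold changes were -0.22 for TNFSF11, -0.08 for TNFRSF11A and -0.01 for TNFRSF11B, and with denosumab they were -0.15, -0.23 and -0.26. In TCam-2, TNFRSF11A differed from vehicle by 0.22 (SE 0.325) with RANKL and by -0.44 (SE 0.342) with OPG, and was at 2.22 ± 0.425 CPM with denosumab. TNFRSF11B had 6 counts in the TCam-2 RANKL libraries, over 3 of the 4, and none in the other 3 TCam-2 groups. TNFSF11 and TNFRSF11B had too few counts to be tested between TCam-2 treatments.

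**Figure D1:**
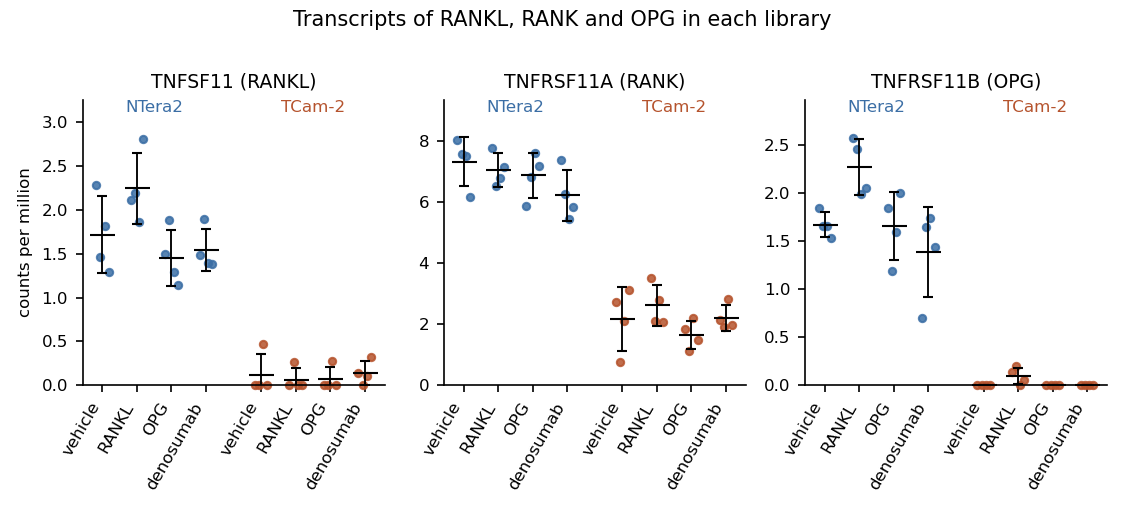
CPM of TNFSF11, TNFRSF11A and TNFRSF11B in each of the 32 libraries by line and treatment; points are the 4 libraries of a group and bars the mean ± SD. TNFRSF11A lies at 7.32 ± 0.807 CPM in NTera2 vehicle and 2.18 ± 1.04 CPM in TCam-2 vehicle, and TNFRSF11B has counts in TCam-2 only with RANKL.

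The comparison of the lines under vehicle asked how the embryonal carcinoma-derived and the seminoma-derived line differ. TCam-2 cells expressed the germ cell regulators SOX17, TFAP2C, PRDM1, TFCP2L1 and NANOS3 far above NTera2, and NTera2 cells expressed SOX2, DNMT3B, GDF3 and TNFRSF8 (CD30) far above TCam-2. SOX17, a determinant of human germ cell fate, was at 163 ± 26.4 CPM in TCam-2 and had 2 counts in NTera2, a ratio of 5210 (counting interval 1440 to 43000). TFAP2C was at 1430 ± 87.5 CPM against 20.2 ± 1.3 CPM (log2 fold change 6.15, SE 0.0844, edgeR adjusted p = 4.64e-18). SOX2 was at 2.53 ± 1.05 CPM against 302 ± 35.5 CPM (-6.93, SE 0.176, edgeR adjusted p = 3.29e-15). POU5F1 was present in both lines, at 2040 ± 244 and 1330 ± 126 CPM (0.62, SE 0.0821, edgeR adjusted p = 3.33e-06), and NANOG was at 574 ± 31.6 and 61.6 ± 6.17 CPM. EdgeR called 12813 of 16816 genes, 6282 higher and 6531 lower in TCam-2, 13040 genes had an unadjusted p under 0.05, and DESeq2 called 14676.

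The genes with the largest differences were present in one line and near or at 0 counts in the other. Higher in TCam-2 was PRAME, a cancer-testis antigen, at 1253 ± 147 CPM against 0.185 ± 0.141 CPM (log2 fold change 12.63, SE 0.194, edgeR adjusted p = 1.79e-17). IGF1 was at 513 ± 36.1 CPM in TCam-2 and had 2 counts in NTera2, a ratio of 16400 (counting interval 4530 to 135000). EID1 was at least 1730-fold higher, XAGE2 at least 903-fold, TCL1A at least 764-fold, ZNF707 at least 676-fold, RBMXL2 at least 673-fold and DPEP3 at least 655-fold, each without counts in NTera2. PTPRZ1, a receptor phosphatase of neural cells, was at 166 ± 22.1 CPM in NTera2 and at least 2770-fold lower in TCam-2. CECR2 was at least 1890-fold lower, HDHD5 at least 1800-fold, MAP2 at least 1540-fold, TMCO1 at least 1070-fold, OCIAD2 at least 748-fold, FEZF1 at least 690-fold, THBS2 at least 683-fold and HPAT5 at least 642-fold.

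CECR2 and HDHD5 are neighbours on chromosome 22, and their region was looked at after these values were seen. IL17RA, TMEM121B, HDHD5, ADA2 and CECR2, between 17084954 and 17558151 (hg38), had 4 counts in all over the 16 TCam-2 libraries. Over the 16 NTera2 libraries the same genes were at 13.4, 7.3, 103, 37.3 and 113 CPM. The genes that follow were expressed in both lines, with ATP6V1E1 at 91.1 CPM in NTera2 and 211 CPM in TCam-2, and BCL2L13 at 54 and 87.9 CPM.

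**Figure D2:**
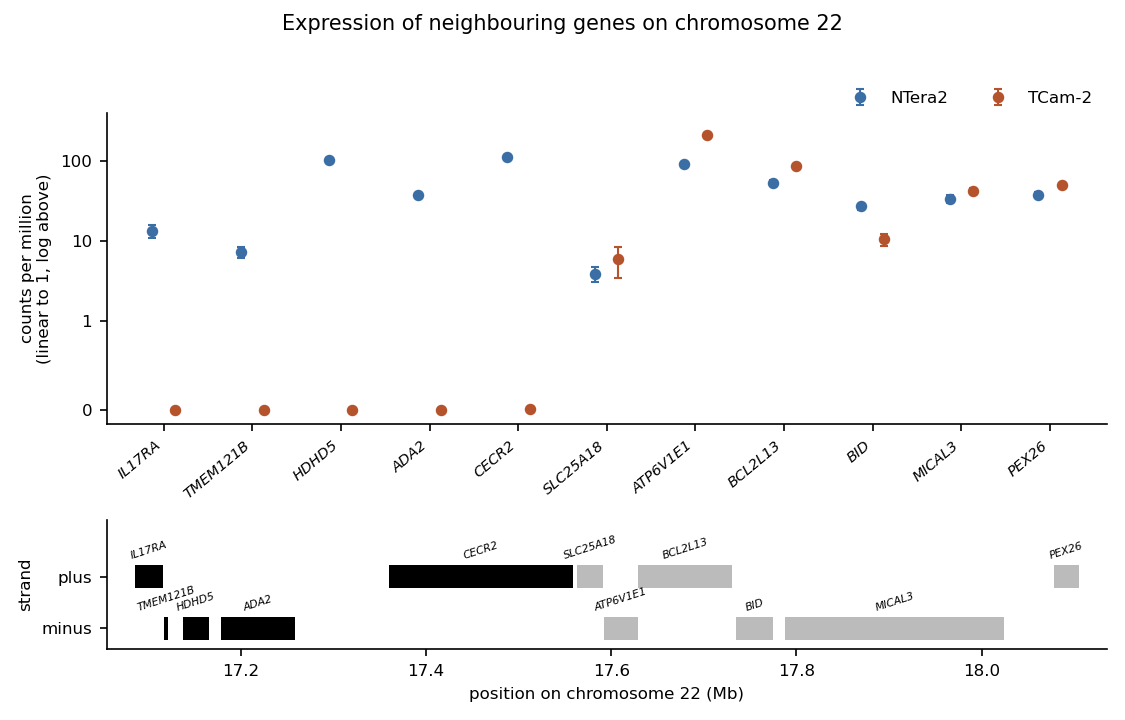
Mean ± SD CPM over the 16 libraries of each line for 11 neighbouring genes of chromosome 22, on an axis that is linear up to 1 and logarithmic above, with a map of the genes (hg38) where black marks the 5 genes almost without counts in TCam-2. IL17RA, TMEM121B, HDHD5, ADA2 and CECR2 have 4 counts in all in TCam-2, while BCL2L13 and the genes beside it are expressed in both lines.

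Among the gene lists, seminoma and primordial germ cell markers were higher in TCam-2 (camera adjusted p = 8.26e-05, 0.0573 with an estimated correlation, median log2 fold change 5.21), with 12 of 15 tested members higher, 1 lower and 2 not called, and the same counts adjusted over the list alone. The median stays the same with TCL1A, which had no counts in NTera2, at its bound. CXCR4 was higher by 6.19, KLF4 by 3.55 and KIT by 1.71 on the log2 scale, and DPPA3 was the lower member (-5.62). The 13 mitochondrially encoded mRNAs were lower in TCam-2 (camera adjusted p = 0.0314, 0.762 with an estimated correlation, median -0.73, 12 of 13 called lower, also adjusted over the list alone), among them MT-ATP6 at 901 CPM against 1725 CPM. Neither list passed with an estimated correlation, and without TCam-2 vehicle replicate 2 the mitochondrial list had an adjusted p of 0.0528. Adjusted over the list alone, 1 more member passed in each of the NF-kB, integrated stress and hypoxia lists than over all genes. Hypoxia and glycolysis genes missed the threshold (camera adjusted p = 0.0515; 11 of 17 higher, LDHA at 707 CPM against 44.1 CPM).

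Most of the other lists held genes that differed in both directions. The cancer-testis and immune cell lists, with 2 tested members each, were too small for camera's test. Of the pluripotency list 6 were higher and 9 lower in TCam-2 (UTF1 2.36, DPPA2 4.61, LIN28A -2.13, GDF3 -3.21), and of the embryonal carcinoma markers 5 were higher and 8 lower (DNMT3L 6.19, CDH1 3.20, TNFRSF8 -5.18, LEFTY2 -5.63). The counts of members higher and lower were 6 and 9 for the RANKL axis (GAB2 2.61, TRAF5 -2.29), 8 and 6 for NF-kB targets (NFKB2 4.21, TNFAIP2 -4.41) and 3 and 1 for osteoclast genes (CLCN7 -1.47). They were 5 and 13 for the cell cycle (MYBL2 2.33, CCND1 -6.01), 7 and 6 for p53 targets (PHLDA3 3.43, MDM2 1.44), 5 and 4 for somatic and extraembryonic genes (GATA4 7.35), and 2 and 0 for the 2 cancer-testis genes tested. They were 5 and 7 for interferon genes (B2M -4.18), 13 and 4 for the integrated stress response (TRIB3 3.10), 5 and 2 for heat shock genes (BAG3 2.34, HSPB1 -2.06), and 6 and 9 for cholesterol synthesis (LSS -1.56). They were 7 and 4 for immediate early genes (EGR1 3.00, JUN -3.05), 6 and 5 for WNT and TGF-beta targets (RNF43 3.37), 6 and 9 for epithelial, mesenchymal and invasion genes (CDH2 2.83), 8 and 10 for ribosomal proteins (RPL8 1.31, RPL5 -0.76) and 5 and 1 for histones (H1-2 2.81). Markers of fibroblasts were split 2 and 4 (COL1A2 8.76, THY1 -3.82), of immune cells 1 and 1 (ITGAM 1.14, CD74 -3.79), and of Sertoli, Leydig and endothelial cells 2 and 4 (AMH -3.57). For fibroblast markers the median was negative and the mean positive, for heat shock genes the reverse, and for WNT and TGF-beta targets both were negative while camera's direction was up.

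**Figure D3:**
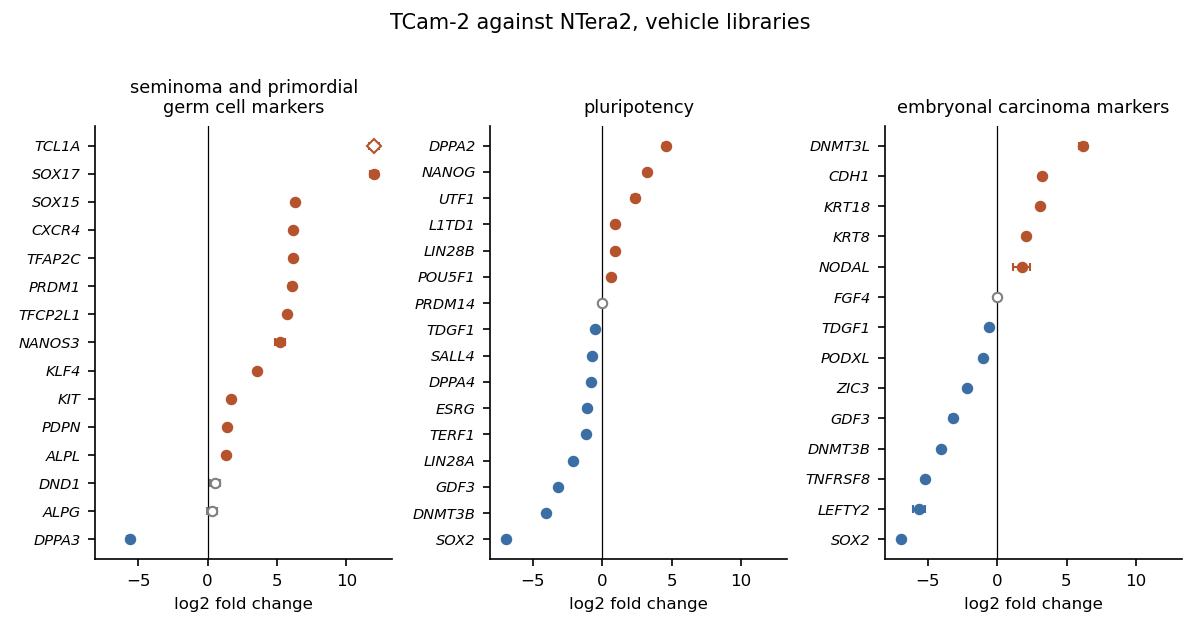
Log2 fold change ± SE of TCam-2 against NTera2 under vehicle (4 libraries each) for seminoma and germ cell, pluripotency and embryonal carcinoma markers; orange is higher and blue lower in TCam-2 past edgeR's threshold, open grey is not past it, and the open diamond is the fitted value of TCL1A, which had no counts in NTera2. SOX2 lies at -6.93 and TFAP2C at 6.15.

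RANKL against vehicle in NTera2 asked whether added ligand changes gene expression in an embryonal carcinoma line with mRNA of its receptor. Mitochondrially encoded mRNAs rose with RANKL as a list (camera adjusted p = 0.00637, 0.975 with an estimated correlation, median log2 fold change 0.14, 12 of 13 positive), with MT-CO2 at 6162 ± 613 CPM against 5615 ± 205 CPM, MT-ATP6 at a log2 fold change of 0.18 and MT-ND2 at 0.16. No member passed adjusted over the list alone, and 7 did with the replicate block. The list's call also ended without vehicle replicate 2 (0.0989), without RANKL replicate 1 (0.238), without RANKL replicate 4 (0.0796), with fry (0.62) and after a correction for GC content and length that was chosen after the data were seen (0.44). With the block the ribosomal protein list also passed, as lower (camera adjusted p = 0.0429), but not with an estimated correlation (0.929).

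No single gene passed edgeR's threshold in that comparison. Of 17351 genes edgeR called 0 (smallest adjusted p 0.368), DESeq2 called 0, and 1787 genes had an unadjusted p under 0.05, 677 higher and 1110 lower. After the correction for GC content and length 578 were higher and 564 lower, and without vehicle replicate 2 the count was 946. With the block edgeR also called 0 genes (smallest adjusted p 0.0521), and 2834 had an unadjusted p under 0.05. The smallest p belonged to genes not past the threshold, among them PPM1N (log2 fold change -1.09), SHISA2 (-0.58), SPHK2 (-0.49), CAPN15 (-0.48), STK11 (-0.35, 73.5 against 94.5 CPM), TBL3 (-0.31), RBAK (0.43) and ATP5PO (0.26). The pluripotency factor SOX2 was at -0.22 and UTF1 at -1.04. Of the pluripotency list 11 of 16 members were positive (median 0.02), and UTF1 lay at 2.57 ± 1.13 CPM in vehicle libraries. The signalling kinase SRC was at -0.24, the NF-kB subunit NFKB1 at 0.16 and the NF-kB target IER3 at -0.26. MKI67, a proliferation marker, was at 0.15 (288 ± 21.5 against 261 ± 9.14 CPM, 4 of 4 pairs, edgeR adjusted p = 0.383). Adjusted over the list alone, 1 gene of the RANKL axis, 2 of pluripotency, 3 WNT and TGF-beta targets and 2 ribosomal protein genes were lower, and 1 interferon gene was higher and 1 lower. With the block these counts changed, to 2 higher and 4 lower for pluripotency, 7 lower for ribosomal proteins, 2 lower for interferon genes, 1 higher for WNT and TGF-beta targets, and from 0 to 5 higher and 2 lower of 11 heat shock genes, 2 higher for the cell cycle, 2 lower for embryonal carcinoma markers and 1 lower each for osteoclast and cholesterol genes. Among genes of at least 10 CPM the median SE was 0.0916.

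OPG against vehicle in NTera2 asked whether blocking RANKL changes expression in cells with a low level of its mRNA. Ribosomal protein mRNAs fell as a list (camera adjusted p = 2.77e-10, 0.333 with an estimated correlation, median -0.07, 28 of 28 negative), with RPL13 at 915 CPM against 1053 CPM, RPS9 at -0.15 and RPL35 at -0.14. Mitochondrially encoded mRNAs rose (camera adjusted p = 1.35e-05, 0.436 with an estimated correlation, median 0.13, 12 of 13 positive), with MT-CYB at 1993 CPM against 1812 CPM and MT-CO3 at 0.15. Cholesterol synthesis genes were lower relative to other genes (camera adjusted p = 0.00524, 0.197 with an estimated correlation, median -0.06, 14 of 17 negative), with FDFT1 at -0.11, FDPS at -0.12 and MVD at -0.24. So were integrated stress response genes (camera adjusted p = 0.00704, 0.209 with an estimated correlation, median -0.07, 15 of 18 negative), with TRIB3 at -0.17 and SESN2 at -0.10.

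None of these 4 lists had a member past the threshold adjusted over the list alone, while with the block 7 mitochondrial mRNAs were higher and 3 ribosomal protein mRNAs lower. None of the lists passed with an estimated correlation or with fry. Without vehicle replicate 1 the cholesterol list had a camera adjusted p of 0.166 and the stress list 0.0671, and the stress list also ended without vehicle replicate 4 (0.104) and without OPG replicate 3 (0.0695). EdgeR called 0 of 17351 genes (smallest adjusted p 1), DESeq2 called 0, and 291 genes had an unadjusted p under 0.05 (117 to 698 without 1 library, 757 with the block). The smallest p belonged to COX5B (-0.27), TMA7 (-0.26), TMSB10 (-0.18), TOMM7 (-0.18), RPL41 (-0.18) and SLIT3 (0.71), none past the threshold. POU5F1 was at 1200 ± 124 CPM against 1330 ± 126 CPM, SOX2 at -0.15 and NFKB1 at 0.15. Of the 16 pluripotency genes tested 8 were positive and 8 negative.

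Denosumab against vehicle in NTera2 asked the same with an antibody. All 13 mitochondrially encoded mRNAs lay above vehicle, and as a list they rose (camera adjusted p = 2.56e-13, 0.148 with an estimated correlation, median log2 fold change 0.25, range 0.16 to 0.31; 11 of 13 past the threshold adjusted over the list alone, 13 with the block). MT-CO2 was at 6583 ± 271 CPM against 5615 ± 205 CPM (0.24, SE 0.0526) and MT-CO3 at 3898 ± 197 CPM against 3278 ± 146 CPM (0.26, SE 0.0551). Cholesterol synthesis genes fell (camera adjusted p = 0.00405, 0.145 with an estimated correlation, median -0.09, 14 of 17 negative; 2 adjusted over the list alone), with MVD at 81.8 ± 14.8 CPM against 114 ± 21.5 CPM, DHCR7 at -0.20 and SREBF2 at -0.14. Osteoclast genes were lower relative to other genes (camera adjusted p = 0.0218, 0.293 with an estimated correlation, median -0.31, 5 of 6 negative, 3 adjusted over the list alone), with JDP2 at -0.51, MMP9 at -0.47, TCIRG1 at -0.34 and CLCN7 at -0.28. So were NF-kB targets (camera adjusted p = 0.0455, 0.337 with an estimated correlation, median -0.12, 11 of 14 negative, 0 adjusted over the list alone), with RELB at -0.51, ICAM1 at -0.36 and NFKBIE at -0.36. The osteoclast list also lay below vehicle with RANKL (median -0.224, 5 of 6 negative) and with OPG (median -0.0891, 6 of 6 negative). It passed camera's threshold in neither. Ligand and inhibitors thus moved its median the same way against the shared vehicle libraries.

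None of the 4 lists passed with an estimated correlation. Leaving out 1 library ended the osteoclast call in 5 of 8 fits (without vehicle replicates 1 and 4 and denosumab replicates 1, 2 and 3, camera adjusted p = 0.14, 0.0736, 0.0602, 0.0558 and 0.13). It ended the NF-kB call without vehicle replicates 2 and 4 and denosumab replicates 1, 3 and 4 (0.0892, 0.135, 0.0669, 0.0888 and 0.184). Neither the osteoclast nor the NF-kB list passed with fry or after the correction for GC content and length. The share of all counts from the 13 mitochondrial mRNAs was 3.79 ± 0.22% with denosumab, 3.52 ± 0.0956% with OPG, 3.496 ± 0.301% with RANKL and 3.22 ± 0.163% with vehicle. In an exact two-sided permutation test chosen after the list result, p was 0.0286 for denosumab, the smallest that 4 against 4 libraries allow, and 0.0858 after adjustment over 6 tests. This test permuted the libraries of both groups freely and ignored the pairing by passage. The exact permutation p was also 0.0286 for OPG (0.0858 adjusted) and was 0.171 for RANKL, and in TCam-2 it was 0.0857 for RANKL and 0.0571 for denosumab. With OPG in TCam-2 the share was 1.995 ± 0.181% against 1.97 ± 0.203%, a difference within the spread of the libraries.

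With denosumab in NTera2 edgeR called 0 of 17351 genes (smallest adjusted p 0.284), and 1258 genes had an unadjusted p under 0.05, 306 higher and 952 lower. After the correction for GC content and length 392 were higher and 491 lower, and the count was 668 without vehicle replicate 2 and 644 without denosumab replicate 1. DESeq2 called 16 genes, 6 higher and 10 lower, and edgeR with the replicate block called 30. The 30 included 8 mitochondrial genes, such as MT-RNR1 (log2 fold change with the block 0.31), MT-RNR2 (0.30), MT-ATP6 (0.28) and MT-ND4 (0.26), and lower genes such as PAK4 (-0.43), RHOB (-0.39), STK11 (-0.33), COX5B (-0.28), GPX4 (-0.26) and DHCR7, chosen after their values were seen. Of the 16 genes of DESeq2, 8 were among the 30, and 6 of the 16 were mitochondrial. Without the block the smallest p belonged to TLNRD1 (-0.52), CAPN15 (-0.55), CYBA (-0.55), CCDC124 (-0.47), MT-CO3, MT-ND2, MT-CYB, MT-CO2, MT-RNR1 and MT-ND5. With the block the immediate early list also passed, as lower (camera adjusted p = 0.0357; JUN -0.35, IER2 -0.31), but not with an estimated correlation (0.263). SOX2 was at -0.24, UTF1 at -1.37, ID1 at -0.42 and MKI67 at 0.11, none past edgeR's threshold. Of the pluripotency list 9 of 16 members were positive (median 0.01). Adjusted over the list alone, 2 pluripotency genes, 1 embryonal carcinoma marker, 1 immediate early gene, 2 WNT and TGF-beta targets and 1 ribosomal protein gene were lower. With the block 5 cholesterol genes, 5 ribosomal protein genes, 3 embryonal carcinoma markers and 2 immediate early genes were lower, 1 heat shock gene was higher and 1 lower, 1 WNT and TGF-beta target was higher, and 1 stress response and 1 somatic or extraembryonic gene were lower.

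**Figure D4:**
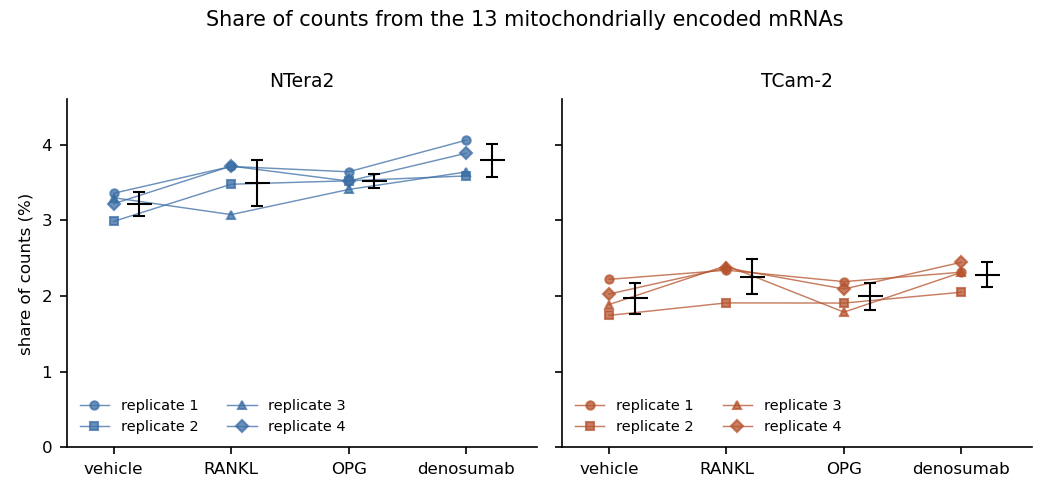
Share of all counts in percent from the 13 mitochondrially encoded mRNAs in each library by line and treatment; lines join libraries of the same replicate number and black marks give mean ± SD of 4. In NTera2 the mean runs from 3.22 ± 0.163% with vehicle to 3.79 ± 0.22% with denosumab, and in TCam-2 from 1.97 ± 0.203% with vehicle to 2.28 ± 0.166% with denosumab.

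RANKL against vehicle in TCam-2 asked whether the ligand acts on a seminoma-derived line. Mitochondrially encoded mRNAs rose as a list (camera adjusted p = 0.000131, 0.737 with an estimated correlation, median 0.17, 11 of 13 positive, 3 adjusted over the list alone and 11 with the block), with MT-ND4L at 828 ± 110 CPM against 627 ± 87.3 CPM and MT-ND4 at 5212 CPM against 4365 CPM. Ribosomal protein mRNAs were lower relative to other genes (camera adjusted p = 0.000131, 0.737 with an estimated correlation, median -0.11, 27 of 28 negative, 0 adjusted over the list alone), with RPL8 at 2887 ± 285 CPM against 3307 ± 498 CPM and RPL18 at -0.23. Without vehicle replicate 4 the ribosomal list had a camera adjusted p of 0.434. RANKL replicates 2 and 4 of TCam-2 had a RIN of 6.1 and 3.7, and without them both lists still passed (camera adjusted p = 3.07e-05 for the mitochondrial and 1.05e-05 for the ribosomal list). With fry neither list passed, and only 1 list was called after the correction for GC content and length. With the block 5 integrated stress response genes and 1 pluripotency gene were lower over the list alone.

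With RANKL in TCam-2 edgeR called 0 of 16621 genes (smallest adjusted p 0.137), DESeq2 called 1, RN7SL1, and 1482 genes had an unadjusted p under 0.05, 740 higher and 742 lower. This count ranged from 711 to 2713 without 1 library and was 1987 with the block, which also called 0 genes (smallest adjusted p 0.0626). Without the 2 libraries of low RIN it was 2514 and with RIN as a covariate 1753, in both with 0 genes called. RN7SL1, a cytosolic signal recognition particle RNA that polyA selection recovers only in part, was at 2.54 ± 1.29 CPM against 8.93 ± 4.84 CPM (edgeR adjusted p = 0.137), and its copies make its counts uncertain. It was also lower with denosumab against the same vehicle libraries (log2 fold change -1.36, edgeR adjusted p = 0.731), so its lower level was not seen with RANKL alone. Others with a small p, not past the threshold, were PCNX1 (0.30), USP8 (0.39), ALDH1L2 (0.60), RAB23 (0.45), NDUFA13 (-0.54), DPM3 (-0.59) and SNHG25 (-1.31). NFKBIA, an NF-kB target, was at -0.21, TNFAIP3 at 0.50, TRAF6, an adaptor of RANK, at 0.27, FAS at 1.46, KIT at 0.22, POU5F1 at -0.18 and MKI67 at 0.19. The median SE of genes of at least 10 CPM was 0.101.

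OPG against vehicle in TCam-2 asked for the effect of blocking ligand in cells with hardly any TNFSF11 counts. No gene list passed camera's test: 10 of 13 mitochondrially encoded mRNAs were positive (median 0.01) and 17 of 28 ribosomal protein mRNAs negative (median -0.01). Without vehicle replicate 4, and without the 2 libraries per line farthest from their groups, the ribosomal list passed as higher. The farthest TCam-2 libraries were vehicle replicate 4 and RANKL replicate 2, so both fits left out the same vehicle library. EdgeR called 0 of 16621 genes (smallest adjusted p 0.253), and 1442 had an unadjusted p under 0.05, 621 higher and 821 lower (994 to 2128 in all without 1 library). With the block it also called 0 (smallest adjusted p 0.0746). DESeq2 called 3, the cytokine receptor gene OSMR and the pseudogenes RPS15P4 and TMSB4XP4, which were named after their values were seen. In edgeR OSMR was at 48.8 CPM against 34.2 CPM (log2 fold change 0.50, SE 0.0993, adjusted p = 0.253). Also not past edgeR's threshold were HDAC5 (-0.62), NDUFA13 (-0.62), CRNDE (-0.84), LUZP1 (0.33), SAYSD1 (0.53), FAM53B (-0.44), NANOS3 (-0.91), UTF1 (-0.89), TCIRG1 (-0.47), JUN (0.56), SLC7A11 (0.40) and MKI67 (0.25, 489 against 407 CPM). Members past the threshold adjusted over the list alone were 1 lower for osteoclast genes, 1 higher and 1 lower for pluripotency, 1 higher for embryonal carcinoma markers, 1 lower for germ cell markers and 1 lower for histones. With the block 2 integrated stress response genes and 1 hypoxia gene were also higher and 1 WNT or TGF-beta target lower.

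Denosumab against vehicle in TCam-2 gave the same pair of lists as RANKL. Ribosomal protein mRNAs were lower relative to other genes (camera adjusted p = 2.63e-07, 0.93 with an estimated correlation, median -0.13, 27 of 28 negative, 0 adjusted over the list alone), with RPS14 at 988 CPM against 1088 CPM. Mitochondrially encoded mRNAs rose (camera adjusted p = 3.85e-06, 0.93 with an estimated correlation, median 0.17, 12 of 13 positive, 3 adjusted over the list alone and 11 with the block), with MT-ND4L at 872 ± 80.1 CPM against 627 ± 87.3 CPM, MT-ATP8 at 0.45 and MT-ND4 at 0.24. Without vehicle replicate 4 the ribosomal list had a camera adjusted p of 0.0546. Neither list passed with fry. EdgeR called 0 of 16621 genes (smallest adjusted p 0.54), DESeq2 called 0, and 1090 had an unadjusted p under 0.05 (540 to 2251 without 1 library). With the replicate block edgeR called MT-ND4L and MT-ND5 (adjusted p = 0.0431), and over the list alone 3 integrated stress response genes and 1 immediate early gene were lower. MTRES1 (-0.71), MRPL14 (-0.32), TIMM17B (-0.27), CCDC138 (0.59), NPAT (0.50) and DDHD2 (0.38) had a small p without passing, MAP3K14 was at -0.43, NFKBIA at -0.20, KIT at 0.25, TOP2A at 0.25 and POU5F1 at -0.15.

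Each inhibitor was also compared with RANKL, which asked whether blocking and adding the ligand differ. In NTera2 the log2 fold change of TNFSF11 with OPG against RANKL was -0.61 (SE 0.278, edgeR adjusted p = 0.913) and that of TNFRSF11B with denosumab against RANKL was -0.72 (SE 0.29, edgeR adjusted p = 1), neither past the threshold. SPP1 (osteopontin) was at 130 CPM with OPG and 153 CPM with RANKL. EdgeR and DESeq2 each called 0 genes in all 4 of these comparisons, and unadjusted p was under 0.05 for 870 (OPG) and 756 (denosumab) genes in NTera2 and 855 and 155 in TCam-2. Without 1 library these counts ranged from 537 to 1325, 657 to 1002, 561 to 1501 and 98 to 255 in that order. No count on all libraries lay clearly above the share of 0.05 expected with no effect. In TCam-2 the interferon-induced IFITM3 was at 176 CPM with OPG and 138 CPM with RANKL (0.36, SE 0.0844, smallest edgeR adjusted p of that comparison 0.887). It was called after the correction for GC content and length (adjusted p = 0.0461), with that and the block (0.00243, 19 genes in all) and without the 2 libraries per line farthest from their groups (0.0227), alternatives chosen after the data were seen. TNFRSF11A was at -0.66 with OPG and -0.23 with denosumab.

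List tests of the inhibitors against RANKL were chosen after the data were seen. Splits of the same libraries, given below, do not exclude chance for the number of lists called. In NTera2, cholesterol synthesis genes were lower with OPG (camera adjusted p = 0.0211) and with denosumab (7.19e-05) than with RANKL, and with denosumab this held with an estimated correlation (adjusted p = 0.0296) while with OPG it did not (0.226). In NTera2 with denosumab, mitochondrial mRNAs were higher (camera adjusted p = 5.47e-05; 0.631 with an estimated correlation) and NF-kB targets lower (0.0105; 0.517). In TCam-2 with OPG, ribosomal protein mRNAs (camera adjusted p = 5.79e-05), hypoxia and glycolysis genes (0.00115) and integrated stress response genes (0.0318) were higher and mitochondrial mRNAs lower (0.000482), and with an estimated correlation these had adjusted p values of 0.596, 0.401, 0.596 and 0.596. With the block the embryonal carcinoma markers (camera adjusted p = 0.0213) and pluripotency genes (0.0234) passed as well, but not with an estimated correlation (0.144 each). No list passed for denosumab against RANKL in TCam-2. Apart from that cholesterol result, no call of a list given above held with an estimated correlation.

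Interactions of line and treatment asked whether the lines responded differently. EdgeR called 0 of 19216 genes for RANKL, OPG and denosumab (smallest adjusted p 0.353, 0.333 and 0.95), with 1004, 999 and 918 genes at an unadjusted p under 0.05. These counts lie close to the share of 0.05 expected with no effect. DESeq2 called 1 gene for RANKL, HBB, and 0 for the others. EdgeR with the block called 1 for denosumab, MT-RNR1, lower in TCam-2 relative to NTera2 (-0.54, adjusted p = 0.0423). Both were named after their values were seen. HBB had an edgeR adjusted p of 0.944 and did not pass the low-count filter in the TCam-2 fit, so its call rests on few counts there. TNFRSF11A had an interaction of 0.28 (SE 0.333, edgeR adjusted p = 0.972) with RANKL, -0.36 (SE 0.349) with OPG and 0.25 (SE 0.344, edgeR adjusted p = 0.965) with denosumab. The smallest p belonged to ANKRD36C (2.27), ACAD11 (1.41) and PARD3B (0.94) for RANKL, CCDC33 (-1.49), MYH3 (-1.57) and SAYSD1 (0.73) for OPG, and FERMT1 (0.76), SUMO2 (-0.33) and LDHB (-0.39) for denosumab, none past the threshold. For others, such as IL2RB, NGB and CDX4, 1 group had few or no counts and the fitted value depends on the prior count, so it is not given.

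The treatment comparisons of a line share their vehicle libraries. Across genes, which are not independent replicates, the fold changes of RANKL and denosumab correlated at 0.731 in NTera2 and 0.82 in TCam-2, where unchanged simulated groups against the same vehicle libraries gave 0.502 and 0.506. With different vehicle libraries in each comparison the values were 0.397 and 0.252. The simulated libraries were not paired, and the split leaves the passages unbalanced, so neither gives the value expected from shared passages alone. The covariances were 0.0142 and 0.0173, against 0.00574 and 0.00669 in the simulation and 0.00914 and 0.00698 with the vehicle libraries split. For RANKL and OPG the correlation was 0.615 in NTera2 and 0.671 in TCam-2 (simulated 0.507 and 0.509, split 0.181 and 0.16), with covariances of 0.00812 and 0.0146 against simulated 0.00572 and 0.00671. For OPG and denosumab it was 0.614 and 0.58 (simulated 0.496 and 0.504, split 0.17 and 0.0544), with covariances of 0.00778 and 0.0115 against simulated 0.00571 and 0.0067.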

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

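The list tests of the interactions and of the inhibitors against RANKL, and the corrections for GC content and length, were chosen only after the results were seen.

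Of 286 groups of 4 libraries examined, 20 held a library far from the other 3 (gap over range above Dixon's 95% critical value), and chance marks about 1 in 20 groups. NTera2 RANKL replicate 1 had 30.5 M counts (30499538), the others of its group 13.7 to 15.1 M. NTera2 denosumab replicate 1 had 21730 genes with counts (others 25070 to 25670) and 19.71% of its counts in the 100 most abundant genes (others 19.01% to 19.09%). That share was 20.23% in TCam-2 vehicle replicate 4 (others 18.89% to 19.06%) and 19.53% in TCam-2 RANKL replicate 2 (others 18.96% to 19.05%). TCam-2 RANKL replicate 2, with a RIN of 6.1, also had a mitochondrial mRNA share of 1.91% (others 2.342% to 2.403%) and a ribosomal list share of 3.325% (others 2.932% to 2.973%).

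In single genes, a library stood apart in CPM for STK11 (NTera2 RANKL replicate 3, 76.3 against 72.53 to 72.7), SLIT3 (NTera2 vehicle replicate 1, 2.772 against 1.762 to 1.898) and MT-CYB (NTera2 denosumab replicate 1, 2290 against 2076 to 2111). The same held for MT-ND5 (NTera2 vehicle replicate 2, 1556 against 1627 to 1635), PPM1N (NTera2 OPG replicate 2, 3.514 against 2.355 to 2.508) and TMEM101 (NTera2 denosumab replicate 4, 23.03 against 21.41 to 21.63). In TCam-2 it held for USP8 (RANKL replicate 2, 58.34 against 66.97 to 67.7), ALDH1L2 (vehicle replicate 3, 13.08 against 7.977 to 8.423), DPM3 (RANKL replicate 1, 11.05 against 15.71 to 16.57) and UTF1 (RANKL replicate 1, 5.862 against 8.631 to 9.149). It also held there for NDUFA13 (OPG replicate 2, 19.73 against 24.19 to 24.45), TIMM17B (vehicle replicate 1, 105.8 against 115 to 116.3) and TCEAL4 (denosumab replicate 4, 6.444 against 8.572 to 8.943).

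4 list tests of the interactions passed camera's threshold. With OPG, integrated stress response genes (camera adjusted p = 0.0441) and ribosomal protein mRNAs (0.00177) moved up in TCam-2 relative to NTera2, and with an estimated correlation both had an adjusted p of 0.756. With denosumab, cholesterol synthesis genes moved up (camera adjusted p = 0.00586) and ribosomal protein mRNAs down (0.00474) in TCam-2 relative to NTera2, and with an estimated correlation both had an adjusted p of 0.945. With the block and an estimated correlation the cholesterol interaction with denosumab had an adjusted p of 0.00673. Of 100 drawn splits, 32 for OPG (real 2, highest other 5) and 51 for denosumab (real 2, highest other 4) called as many lists, so chance cannot be excluded for these counts. The splits ignore the pairing and count lists, so they do not test the cholesterol interaction with the block.

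Mitochondrial mRNAs lay above vehicle with denosumab in both lines. In NTera2 their median log2 fold change was 0.253 before and 0.17 after the correction for GC content and length. The highest camera adjusted p over the fits without 1 library was 1.1e-10, and 1 of 35 splits had a median as far from 0 (real 0.2525, highest other 0.1908). These values argue against a GC and length trend as the whole cause, a single library and, more weakly, chance. The list did not pass with an estimated correlation (adjusted p = 0.148), and the exact test of its share gave 0.0858 after adjustment over 6 tests. Both the splits and the exact test ignore the pairing. In TCam-2 the median was 0.17 before and 0.229 after the correction and the highest leave-one-out adjusted p was 0.00253, but 6 of 35 splits were as far from 0 (real 0.1699, highest other 0.23), so chance cannot be excluded there by splits that ignore the pairing (adjusted p with an estimated correlation 0.93). The share lay above vehicle in 4 of 4 pairs with denosumab in both lines, but also with OPG in NTera2 and RANKL in TCam-2 and in 3 of 4 with RANKL in NTera2, so low vehicle libraries stay open in NTera2, where the list against RANKL had an adjusted p of 0.631 with an estimated correlation (camera 5.47e-05), while with OPG in TCam-2 it did so in only 2 of 4 (1.995 ± 0.181% against 1.97 ± 0.203%), which goes against them there without excluding them. The lines were not shown to differ in the list (camera adjusted p of the interaction 0.931). In edgeR with the block, MT-RNR1, which is not in the list, was lower in TCam-2 relative to NTera2 (interaction -0.54, adjusted p = 0.0423, without the block 0.95). Reads shared with nuclear copies of mitochondrial genes were not tested, so a response to denosumab stays open.

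Cholesterol synthesis genes lay below vehicle with OPG and denosumab in NTera2. After the correction for GC content and length their median log2 fold change was -0.0733 with OPG (before -0.0632) and -0.0803 with denosumab (before -0.0902), which argues against that trend as the whole cause. For denosumab the list was also lower than with RANKL, in a comparison without vehicle libraries (camera adjusted p = 7.19e-05, median -0.107, with an estimated correlation 0.0296). This argues against high vehicle libraries as the whole cause. The RANKL median itself lay above vehicle (0.0421, 10 of 17 positive), so the difference from RANKL does not isolate denosumab. In that comparison 4 of 35 splits called as many lists (real 3, highest other 3). For OPG high vehicle libraries stay open (camera adjusted p against RANKL 0.0211, median -0.0449, with an estimated correlation 0.226). Against vehicle, 3 of 35 splits for OPG (real -0.06316, highest other 0.08128) and 2 of 35 for denosumab (real -0.09016, highest other 0.09454) gave a median as far from 0, so chance cannot be excluded. No biological explanation was tested.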

How the results depend on the processing

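Tests with a correction for GC content and length, without the 2 libraries per line farthest from their groups, with the block and an estimated correlation together, and of lists without 1 library were chosen only after the results were seen. Of the values of 524 named gene results under the alternatives, 8928 kept their side of the threshold, 72 of them with the other sign and past it in neither fit, 111 newly passed and 4 no longer passed, all 4 for ITGAM between the lines. Of the values of 154 list results, 2218 kept their side, 208 of them with the other direction and past it in neither fit, 39 newly passed, 72 no longer passed and 3 reversed. Depth limits what can be said of genes near the floor of 3 counts, such as TNFSF11 and TNFRSF11B in TCam-2.

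Gene counts of 0 became larger in several fits. Without the low-count filter 176 genes (12 higher, 164 lower) were called for RANKL and 237 (14 higher, 223 lower) for denosumab in NTera2, 51, 54 and 28 for RANKL, OPG and denosumab in TCam-2, 1 for NTera2 OPG against RANKL, 3 and 1 for TCam-2 OPG and denosumab against RANKL, and 1, 3 and 32 for the interactions with RANKL, OPG and denosumab. The median prior degrees of freedom was 14.5 in NTera2 and 12.8 in TCam-2 with the filter and infinite without it, although NTera2 OPG stayed at 0 genes, and 171 of the 176, 236 of the 237, 50 of the 51, 51 of the 54 and 28 of the 28 genes had been tested with the filter. At an infinite value a gene's own spread no longer enters its test, so such calls do not rest on the spread of that gene's libraries. The cause of these calls and of the other changes was not tested. DESeq2 called 16 for NTera2 denosumab, 1 for TCam-2 RANKL, 3 for TCam-2 OPG and 1 for the interaction with RANKL. The replicate block gave 30 for NTera2 denosumab, 2 for TCam-2 denosumab and 1 for the interaction with denosumab. The correction for GC content and length gave 1 for TCam-2 OPG and 1 for TCam-2 OPG against RANKL, IFITM3 in both. The same correction with the block gave 1 for NTera2 RANKL (IGFBPL1), 17 for NTera2 denosumab, 4, 8 and 5 for RANKL, OPG and denosumab in TCam-2, 19 for TCam-2 OPG against RANKL and 1 for the interaction with OPG (IFITM3). Without the 2 farthest libraries per line 1 gene was called for TCam-2 RANKL (RN7SL1) and 1 for TCam-2 OPG against RANKL (IFITM3).

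Without 1 library, NTera2 denosumab ranged from 0 to 29 genes, with 29 without vehicle replicate 3 (5 of them among the 30 of the block) and 1 without denosumab replicate 3. TCam-2 RANKL ranged from 0 to 1 (vehicle replicate 4 or RANKL replicate 1), OPG from 0 to 1 (vehicle replicate 3) and denosumab from 0 to 1 (vehicle replicate 1), and the other comparisons with 0 genes stayed at 0. The line comparison ranged from 12425 to 13021 genes without 1 library and gave 12944 with the block and 14676 with DESeq2. That block joined libraries of the same number but of different passages.

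For the lists, an estimated correlation left 0 called in NTera2 RANKL (1 before), NTera2 OPG (4), NTera2 denosumab (4), TCam-2 RANKL (2), TCam-2 denosumab (2) and the line comparison (2), also with the block. Fry left 0 in the same comparisons except NTera2 denosumab, with 2 (mitochondrial and cholesterol, adjusted p = 0.0309 each), and the line comparison, with 20. The GC and length correction, with or without the block, left 0 for NTera2 RANKL, 2 for NTera2 denosumab and 1 for TCam-2 RANKL. The block gave 2 for NTera2 RANKL, 5 for NTera2 denosumab and 3 for the lines (hypoxia and glycolysis added, camera adjusted p = 0.0431), and changed which members passed over the list alone. Between the lines the block joined libraries of the same number, which share no passage, so it is no paired check there. Without the 2 farthest libraries TCam-2 OPG had 1. Without 1 library the counts ranged from 0 to 2 for NTera2 RANKL (0 without vehicle replicate 2 or RANKL replicate 1, 2 without vehicle replicate 1 or 3) and 2 to 5 for NTera2 OPG (2 without vehicle replicate 1). They ranged from 2 to 4 for NTera2 denosumab (2 without denosumab replicate 3), 1 to 3 for TCam-2 RANKL (1 without vehicle replicate 4), 0 to 1 for TCam-2 OPG (1 without vehicle replicate 2 or 4), 1 to 2 for TCam-2 denosumab (1 without vehicle replicate 4) and 1 to 3 for the lines (1 without TCam-2 vehicle replicate 2). Reversed was the ribosomal list in TCam-2 OPG, now higher, without the 2 farthest libraries (camera adjusted p = 0.00635) and without vehicle replicate 4 (0.0215, range without 1 library 0.0215 to 0.982). Both of these fits left out vehicle replicate 4. The somatic and extraembryonic list between the lines reversed with fry (4.1e-06).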

Other observations

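The splits for the 13 comparisons without a called gene and for the lists of TCam-2 OPG, and the test of neighbouring genes almost without counts, were chosen only after the results were seen.

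Genes with at most 3 counts over the 16 libraries of one line and a mean of at least 1 CPM in the other, here called silent, were in part neighbours. In TCam-2 119 of 13038 genes compared were silent and 5 pairs of them were neighbours, where random placement gave 1.09 on average and 9 at most (10000 permutations, p = 0.004). The longest run, IL17RA to CECR2 on chromosome 22 (17084954 to 17558151), held 5 genes with 4 counts in all. It was seen before the test and supplied 4 of the 5 pairs, so the p largely restates it. In NTera2 76 of 12432 genes were silent with 9 neighbouring pairs against 0.459 on average and 5 at most (p = 1e-04, the smallest that the permutations can give), and the longest run was SERPINB12, SERPINB4 and SERPINB3 on chromosome 18 (63542369 to 63661893), with 3 counts in all and at 1.43 to 4.35 CPM in TCam-2. The chromosome 22 run may reflect loss of a segment or shared silencing, and RNA counts do not separate these.

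Other splits of the same libraries were counted to ask whether chance can be excluded. For the lines it can, with 12813 genes for the real split, 0 as the highest other count and 1 of 35 splits as large. For the 10 counts of 0 within a line all 35 of 35 splits were as large, and for the 3 interactions 100 of 100 drawn splits, which says nothing about chance because every split reaches a count of 0. The highest other counts were 162, 0 and 88 for RANKL, OPG and denosumab in NTera2, 1740, 4 and 161 in TCam-2, 461 for NTera2 OPG against RANKL, 0 for the other inhibitor comparisons with RANKL, and 1658, 10 and 399 for the interactions. Splits that call this many genes point to a structure of the samples. Among the 8 splits that parted all 4 same-numbered pairs, too few for a share under 0.05, the real count at an unadjusted p under 0.05 and the highest other were 1787 and 2143, 291 and 1045, and 1258 and 1069 for RANKL, OPG and denosumab in NTera2, and 1482 and 1291, 1442 and 1852, and 1090 and 1292 in TCam-2. The other splits kept same-numbered libraries together in part and reached 4320 for TCam-2 RANKL, but they are more numerous, so a higher maximum does not show an effect of the pairing.

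With the block only 8 splits exist, too few for a share under 0.05. The 30 genes of NTera2 denosumab and the 2 of TCam-2 denosumab each stood against 0 as the highest other, while for NTera2 RANKL the real split gave 0 genes and another 769, and for NTera2 OPG 0 and 11.

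For the counts of lists called, 20 of 35 splits were as large for NTera2 RANKL (real 1, highest other 4), 3 for OPG (real 4, highest other 5) and 2 for denosumab (real 4, highest other 4). In TCam-2 16 of 35 were as large for RANKL (real 2, highest other 4), 35 for OPG (real 0, highest other 4) and 15 for denosumab (real 2, highest other 4), and for the lines 14 (real 2, highest other 3). These splits ignore the pairing, and chance cannot be excluded for any of these 7 counts of lists. With the block the real split was the largest of 8 for RANKL (2, highest other 1), OPG (4, highest other 3) and denosumab (5, highest other 2) in NTera2, while in TCam-2 4, 8 and 4 of 8 were as large, and 8 splits are too few for a share under 0.05. Against RANKL, 20 of 35 splits were as large for NTera2 OPG (real 1, highest other 3) and 4 for NTera2 denosumab (real 3, highest other 3). In TCam-2 4 were as large for OPG (real 4, highest other 5) and 35 for denosumab (real 0, highest other 5). Chance cannot be excluded for these counts either. They count lists and do not test the cholesterol list by itself.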
